A study of Mus musculus with 8 samples.

How the data were processed

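Total RNA of 8 libraries was sequenced from embryonic fibroblasts of FVB/NTac mice, 2 each from uninfected, GMT, Hand2 and GMT_Hand2 cells, 14 days after infection. The labels name a stranded kit with removal of ribosomal RNA. The submitters' processing notes name FastQC 0.11.2, TopHat, Picard 1.127, featureCounts and edgeR, with no version for TopHat, featureCounts and edgeR and no counting or strand setting, and 2 genome builds, hg19 and mm10. Reads of overlapping genes, of antisense partners and of near-identical copies can therefore not be told apart with certainty. The deposited table gives mouse genes with positions. Of 19727 genes matched by symbol to the RefSeq annotation of GRCm38.p6, 19647 (99.59%) overlapped its position, so positions are those of mm10, with starts counted from 1.

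The authors deposited 1 table of 21019 genes. Per the file headers it holds a normalized signal per library, which is a CPM of an effective library size, and for 6 pairs of groups a log2 fold change, an average log2 level and a p-value with its adjusted form. The signals of each library turned out to be whole multiples of the value of 1 read (100% of values within 0.01), between 0.0126 and 0.0222, so the reads were recovered: 43.3 to 84.4 M per library (M, 1e6). Column sums ran from 960313 to 1.06e+06. The deposited log2 and p-value columns of the authors were not used for the results here, apart from a check described under the other observations. A per-sample column that matches no sample of the series was not used here. Entries whose gene symbols had been turned into dates, 27 in number, were left out, which leaves 20992 genes.

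Raw counts and edgeR had been planned as the main test before the data were examined, together with the gene lists, the rule for naming genes, and the alternatives, except those said to be added. Since the table holds normalized values, the test planned for such a table was the main one, although reads could be recovered. It was limma 3.58.1 in R 4.3.3 on log2(value + 1), with a mean-variance trend, for genes at 1 or more in at least 2 of 8 libraries (14038 genes). A single linear model over the 4 groups, without a replicate term, gave 4 residual degrees of freedom before moderation. The comparisons were GMT_Hand2 with GMT, Hand2 with uninfected, GMT with uninfected, GMT_Hand2 with uninfected, GMT_Hand2 with Hand2, and the difference of the Hand2 effects with and without GMT. Tests were 2-sided with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. Adjusted p-values are those of limma unless another tool is named.

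Genes of 26 lists (498 different genes, 407 tested) were chosen from general knowledge before the data were examined: the delivered factors, sinoatrial pacemaker, sarcomere, calcium handling and working-myocardium excitability, atrial, ventricular, endogenous cardiac transcription factors, fibroblast and extracellular matrix, smooth muscle, skeletal muscle, cell cycle, fatty acid and oxidative metabolism, interferon response, inflammatory cytokine and chemokine, sympathetic neuron, neuronal, endothelial, macrophage and blood, epithelial, adipocyte, cartilage and bone, limb and branchial arch patterning, Hox genes, BMP, TGF-beta and Notch signalling, immediate early and dissociation stress, and p53 and senescence. Each list with at least 5 tested genes, apart from the delivered factors, was tested against all other genes with camera at a preset correlation of 0.01 and again with the correlation estimated from the data, adjusted over 25 lists. No list was called in any comparison with the estimated correlation. Counts per list are given over all genes and adjusted over the list alone. A list of 20 glial genes was added after the data were seen and tested by itself.

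The text names the delivered factors, up to 4 genes per list with the largest changes among those that passed (mean of at least 1, groups not overlapping) in GMT_Hand2 against GMT, Hand2 against uninfected and GMT against uninfected, the 5 largest rises and falls that passed in each comparison (higher group mean of at least 5, groups not overlapping except for the interaction), and genes fixed in advance: Hcn4, Isl1, Shox2, Tbx3, Tbx18, Myh6, Myl7, Nppa, Tnnt2, Actc1, Nkx2-5, Col1a1, Postn and Mki67. Genes named outside this rule, the glial genes, were chosen after their values were seen. Groups of 2 libraries allow no test of single deviating libraries and no test by other splits of the libraries.

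Alternatives were size factors by relative log expression, DESeq2 1.42.0 on the recovered reads, no filter on low values, a fit of only the compared groups, the replicate number as a block, a pseudocount of 0.1, a log2 fold of at least 1, and leaving out each library of the compared groups in turn. The edgeR 4.0.16 quasi-likelihood test, planned for counts, was run on the recovered reads after the data were seen. Added then as well were edgeR with the block, a test of genes at 1 or more in 2 infected libraries, leaving out libraries of other groups, and refits of all interaction genes of the closing section. On reads simulated for GMT_Hand2 against GMT (13981 genes tested) limma found 3.75% of genes changed by log2 1, 78.3% by log2 2 and 93.3% by log2 3, with 9 false calls of 115. DESeq2 (15954 genes) found 36.3, 98.3 and 100%, with 83 false calls of 231, and edgeR (15711 genes) 1.25, 78.3 and 93.3%, with 6 of 110. Camera called a list raised in the simulation and 0 of 50 unchanged lists. Genes were simulated independently of each other, so this cannot show how the preset correlation behaves where genes of a list vary together. In the data the estimated correlation ran from -0.08 for the neuronal list to 0.87 for the interferon list. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.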

Results

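Total RNA was sequenced from embryonic fibroblasts of FVB/NTac mice, taken at mid-gestation and collected 14 days after infection. The 8 libraries fall into 4 groups of 2. Uninfected fibroblasts are the starting cells. GMT cells received Gata4, Mef2c and Tbx5, cardiac transcription factors that turn fibroblasts towards cardiomyocytes, together with GFP for sorting. Hand2 cells received Hand2, a basic helix-loop-helix factor of heart, limb and sympathetic neuron development, fused to GFP. GMT_Hand2 cells received both and were, by the sample labels, sorted by the GFP on Hand2, whereas the series' design text describes 4-factor cells by an Hcn4 reporter. If that reporter chose the cells, any difference of GMT_Hand2 from another group could come from that choice, which was not tested. The shared protocol describes sorted GFP-positive cells, although the labels name no source of GFP for the uninfected cells. The series is about how Hand2 redirects GMT reprogramming towards a pacemaker-like state, so GMT_Hand2 against GMT was the first comparison.

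The uninfected libraries held 69.2 and 84.4 M assigned reads (M, 1e6), the GMT libraries 49.1 and 43.3, the Hand2 libraries 45.4 and 48.1, and the GMT_Hand2 libraries 49.2 and 49.1. Between 12714 and 13202 genes reached a normalized CPM of 1 in a library. Levels are given in that unit as mean ± SD of 2 libraries, folds are ratios of those means, and log2 changes are differences of mean log2(level + 1), which understate the change of low genes. Across genes, which are not independent replicates, r of the log levels within a group was 0.986 for uninfected, 0.951 for GMT, 0.952 for Hand2 and 0.969 for GMT_Hand2. GMT replicate 1 and GMT_Hand2 replicate 1 correlated at 0.958, and replicates 2 of these groups at 0.955, both above the 0.951 within GMT. The labels do not say that the replicates are separate cultures, so the p-values measure only the spread between these samples, which could be that of technical repeats.

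The 4 delivered factors followed the labels in every library. Hand2 (chromosome 8, 57320983 to 57324517) stood at 2.15 and 2.29 in the uninfected libraries and 2.71 and 3.51 in the GMT libraries, against 2598 and 1861 in Hand2 and 942 and 933 in GMT_Hand2. Gata4 (chromosome 14, 63198915 to 63245260) read 3.92 and 2.13 in uninfected and 2.34 and 2.12 in Hand2 cells, but 219.5 and 361 in GMT and 646 and 684 in GMT_Hand2. Tbx5 (chromosome 5, 119834663 to 119885218) went from 2.04 and 1.60 in uninfected and 0.779 and 1.50 in Hand2 to 356 and 619.8 in GMT and 1072 and 1072 in GMT_Hand2. Mef2c (chromosome 13, 83504034 to 83667079) was already read in uninfected cells, at 54.1 and 54.6, with 21.1 and 37.9 in Hand2, 152 and 195 in GMT and 429 and 248 in GMT_Hand2. These values count delivered and endogenous transcripts together, and by the sample labels Hand2 was part of the sort in the Hand2 and GMT_Hand2 groups.

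Cells given Hand2 on top of GMT had 3 sarcomere genes at higher levels than cells given GMT alone. Tnnt2, the cardiac troponin T gene (chromosome 1, 135836334 to 135852268), stood at 1831 ± 352 in GMT_Hand2 against 411 ± 21.3 in GMT, 4.46-fold higher (log2 2.14, SE 0.22, limma adjusted p = 0.0187). Tnnc1, which encodes the calcium-binding troponin C of slow and cardiac muscle (chromosome 14, 31208312 to 31211711), rose 16.3-fold to 186 ± 99.4 (log2 3.84, SE 0.40, adjusted p = 0.0188), and Tnni1, the slow skeletal troponin I gene of early heart, rose 5.31-fold (log2 2.37, SE 0.27, adjusted p = 0.0246). The alpha-cardiac actin gene Actc1, at 145 ± 41.5 against 42.9 ± 16.3, and the atrial myosin heavy chain gene Myh6, at 287 ± 78.2 against 29.0 ± 25.7, were higher in both GMT_Hand2 libraries but did not pass (adjusted p = 0.0830 and 0.0798). With the replicate number as a block, Myh6 passed (limma adjusted p = 0.0240) and Actc1 did not. Of 27 sarcomere genes tested, 3 rose, 0 fell and 24 did not pass (8 higher and 1 lower adjusted over the list alone), with a median log2 of 0.51 (camera adjusted p = 7.68e-06, adjusted p = 0.240 with an estimated correlation).

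Myl7, the atrial myosin light chain gene (chromosome 11, 5896637 to 5898782), was at 201 ± 70.3 in GMT_Hand2 and 208 ± 92.5 in GMT (log2 -0.02, SE 0.36, adjusted p = 1). Nppa, which encodes atrial natriuretic peptide, was at 209 and 39.0 against 103 and 62.1 (log2 0.18, adjusted p = 0.998). By limma, 0 of 14 atrial genes passed (1 higher and 1 lower adjusted over the list alone), and the atrial median was -0.06 (camera adjusted p = 0.405).

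Among genes of the sinoatrial pacemaker, Popdc2 and Bves passed. Both encode Popeye-domain membrane proteins that bind cyclic AMP and are needed for steady pacemaking. Popdc2 (chromosome 16, 38362173 to 38378216) rose 12.7-fold, from 6.36 ± 2.82 in GMT to 80.9 ± 17.5 in GMT_Hand2 (log2 3.52, SE 0.35, adjusted p = 0.0187, but 0.0611 with edgeR), and Bves rose 4.84-fold to 35.8 ± 5.54 (log2 2.13, SE 0.22, adjusted p = 0.0188). Hcn4, the main channel gene of the pacemaker current (chromosome 9, 58823512 to 58860955), was 41.9-fold higher, with 64.9 and 244 in the GMT_Hand2 libraries against 0.976 and 6.40 in GMT. It did not pass in limma (log2 5.05, SE 0.84, adjusted p = 0.0669) or edgeR (adjusted p = 0.203), and passed with DESeq2 (adjusted p = 0.00480). With the replicate number as a block, a pairing that no label gives, Hcn4 passed in limma (adjusted p = 0.0127) and edgeR (adjusted p = 0.0180). Since the design text names an Hcn4 reporter and the sample labels GFP fused to Hand2, it is open whether Hcn4 was used to choose the cells. The pacemaker transcription factors did not pass: Tbx18 stood at 80.7 ± 22.4 against 44.5 ± 10.8, Tbx3 at 32.4 ± 11.5 against 25.2 ± 5.80 and Shox2 at 2.27 ± 0.693 against 4.34 ± 3.66 (adjusted p = 0.246, 0.922 and 0.869). Isl1 was at most 0.465 and Nkx2-5 at most 0.108 in any library, too low to be tested. Of 17 pacemaker genes tested, 2 rose, 0 fell and 15 did not pass (7 higher and 0 lower adjusted over the list alone), with a median of 0.69 (camera adjusted p = 0.00148, adjusted p = 0.240 with an estimated correlation).

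**Figure D1:**
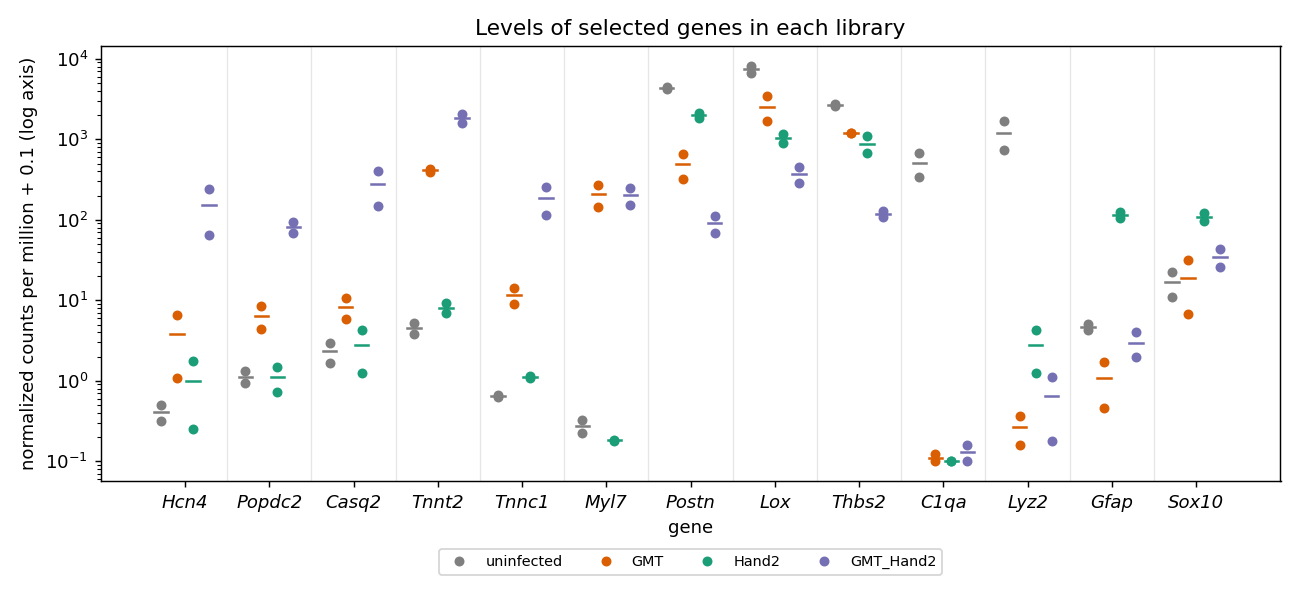
Normalized CPM plus 0.1, on a log axis, of 13 genes in the 8 libraries, coloured by group, with a bar at each group mean. Hcn4, Popdc2, Casq2, Tnnt2 and Tnnc1 are highest in GMT_Hand2, Myl7 is alike in GMT and GMT_Hand2, Postn, Lox and Thbs2 are lowest in GMT_Hand2, C1qa and Lyz2 are high in uninfected cells only, and Gfap and Sox10 are highest in Hand2 cells.

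Casq2, which encodes the calcium-storing calsequestrin of the cardiac sarcoplasmic reticulum (chromosome 3, 102086455 to 102146512), rose 33.7-fold, from 8.20 ± 3.52 to 276 ± 178 (log2 4.80, SE 0.62, adjusted p = 0.0346, but 0.0950 with edgeR), while calcium handling and excitability genes as a list were not called (1 of 18 rose, 2 higher and 0 lower adjusted over the list alone, median 0.20, camera adjusted p = 0.569). The myoglobin gene Mb rose 17.4-fold (log2 2.99, SE 0.33, adjusted p = 0.0216), the sole gene of 21 in fatty acid and oxidative metabolism to pass (1 higher and 1 lower adjusted over the list alone, median 0.14, camera adjusted p = 0.143). Aldh3a1, an aldehyde dehydrogenase gene (chromosome 11, 61208742 to 61218416), showed the largest log2 rise after Hand2 itself, 117-fold from 1.66 ± 1.33 to 194 ± 2.20 (log2 6.29, SE 0.41, adjusted p = 0.00543). The Wnt inhibitor gene Sfrp5, a marker of the inflow region of the heart, rose to 45.4 and 121 in the GMT_Hand2 libraries from 2.23 and 0.800 (log2 4.96, adjusted p = 0.0187), and the tachykinin gene Tac2 to 15.1 and 46.9 from 0.179 and 0.311 (log2 4.48, adjusted p = 0.0338).

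Several matrix genes fell from GMT to GMT_Hand2. Thbs2, a matricellular thrombospondin gene (chromosome 17, 14665500 to 14694262), fell 10.1-fold, from 1188 ± 9.50 to 118 ± 13.9 (log2 -3.32, SE 0.24, adjusted p = 0.00982). The small proteoglycan gene Bgn fell 6.49-fold, the collagen cross-linking enzyme gene Lox fell 6.91-fold and the PDGF receptor gene Pdgfrb fell 2.90-fold (adjusted p = 0.00982, 0.0471 and 0.0355). Postn, the periostin gene of activated fibroblasts, was at 90.7 ± 30.6 against 493 ± 241 and did not pass (log2 -2.38, adjusted p = 0.0598), nor did the collagen gene Col1a1, at 3567 ± 101 against 4654 ± 1161 (adjusted p = 0.852). With the replicate number as a block, Postn passed (limma adjusted p = 0.0309) and Col1a1 did not. Of 30 fibroblast and extracellular matrix genes tested, 0 rose, 3 fell and 27 did not pass (0 higher and 8 lower adjusted over the list alone), with a median of -0.64 (camera adjusted p = 6.79e-07, adjusted p = 0.240 with an estimated correlation). The other large falls were the protocadherin gene Pcdh19 (20.7-fold, adjusted p = 0.00176), the interleukin-33 receptor gene Il1rl1 (40.9-fold), Plac8 (17.3-fold) and the growth factor gene Fgf7 (15.4-fold).

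Among cell cycle genes Tyms, the thymidylate synthase gene, was the sole one to pass over all genes, 2.29-fold higher at 58.8 ± 0.456 against 25.7 ± 0.0300 (log2 1.16, SE 0.17, adjusted p = 0.0447). The proliferation marker gene Mki67 was at 148 ± 35.0 against 77.6 ± 32.4 and did not pass (log2 0.96, adjusted p = 0.294). Of 26 cell cycle genes tested, 1 rose, 0 fell and 25 did not pass (17 higher and 0 lower adjusted over the list alone), all 26 had a positive log2 change, and the median was 0.87 (camera adjusted p = 2.85e-14, adjusted p = 0.240 with an estimated correlation).

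In total, limma placed 64 genes higher and 46 lower in GMT_Hand2 than in GMT, 110 of 14038 tested, of which 108 changed at least 2-fold. The delivered factors were not level: Gata4, Tbx5 and Mef2c were 2.29, 2.20 and 1.95 times as high in GMT_Hand2 as in GMT without passing (limma adjusted p = 0.169, 0.171 and 0.377). Hand2 rose 302-fold (limma adjusted p = 6.81e-05). Of the 4, 4 were higher and 0 lower adjusted over the list alone. Changes from GMT to GMT_Hand2 were not separated from the higher levels of Gata4, Tbx5 and Mef2c. The count depended on the fit: the compared groups alone, with 2 residual degrees of freedom, gave 1 gene, and the replicate number as a block gave 332. Fits without 1 library leave a group of 1 and have fewer degrees of freedom. A lower count than with all libraries does therefore not by itself show that the calls rested on the library left out. Each of these fits loses equally many degrees of freedom, so differences among them have another source. Leaving out a library also takes its group out of the estimate of the spread. How much this mattered was not tested. The edgeR test, planned for counts and run on the recovered reads once the data had been seen, called 41 genes, 39 of them shared with limma. With it 8 genes named above did not pass: Popdc2, Casq2, Mb and Sfrp5 (adjusted p = 0.0611, 0.0950, 0.0905 and 0.165) and Tac2, Lox, Pdgfrb and Tyms (0.120, 0.0793, 0.0656 and 0.0669). Of 20 named genes that passed in limma, Hand2 and Pcdh19 passed in all 8 fits that left out 1 library. Without GMT replicates 1 and 2, 8 and 7 of the 20 passed, without either GMT_Hand2 library 2 of the 19 still tested, without either uninfected library 3 of 20, and without either Hand2 library 18.

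Camera called 4 of 25 lists between GMT_Hand2 and GMT, 3 higher and 1 lower, and 0 with an estimated correlation. No gene of the other lists passed in limma, apart from the calcium handling and metabolism lists with 1 gene each. Medians were 0.19 for ventricular genes, -0.06 for endogenous cardiac transcription factors, -0.16 for smooth muscle, 0.13 for skeletal muscle, 0.15 for the interferon response, 0.07 for inflammatory cytokines and chemokines, 0.17 for sympathetic neurons, -0.53 for neuronal genes. They were 0.00 for macrophage and blood genes, -0.37 for epithelial genes, -0.26 for adipocyte genes, -0.13 for cartilage and bone, -0.28 for limb and branchial arch patterning, -0.09 for Hox genes, -0.17 for BMP, TGF-beta and Notch signalling, -0.32 for immediate early and dissociation stress genes, -0.13 for p53 and senescence. Endothelial genes came nearest to a call, with a median of -0.32 (camera adjusted p = 0.0620). The median and the camera direction had opposite signs for the cardiac transcription factors, the inflammatory genes, the macrophage genes and cartilage and bone. Without GMT replicate 1 the skeletal muscle (median 1.02), inflammatory (-0.34), limb (-0.21) and immediate early (-0.90) lists were called as well, and without GMT replicate 2 the calcium handling (0.45), smooth muscle (-0.46), metabolism (0.34) and p53 (-0.32) lists were. Without GMT_Hand2 replicate 2 the immediate early (-0.61) and adipocyte (-0.29) lists were called, and without either uninfected library the immediate early list (-0.32).

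**Figure D2:**
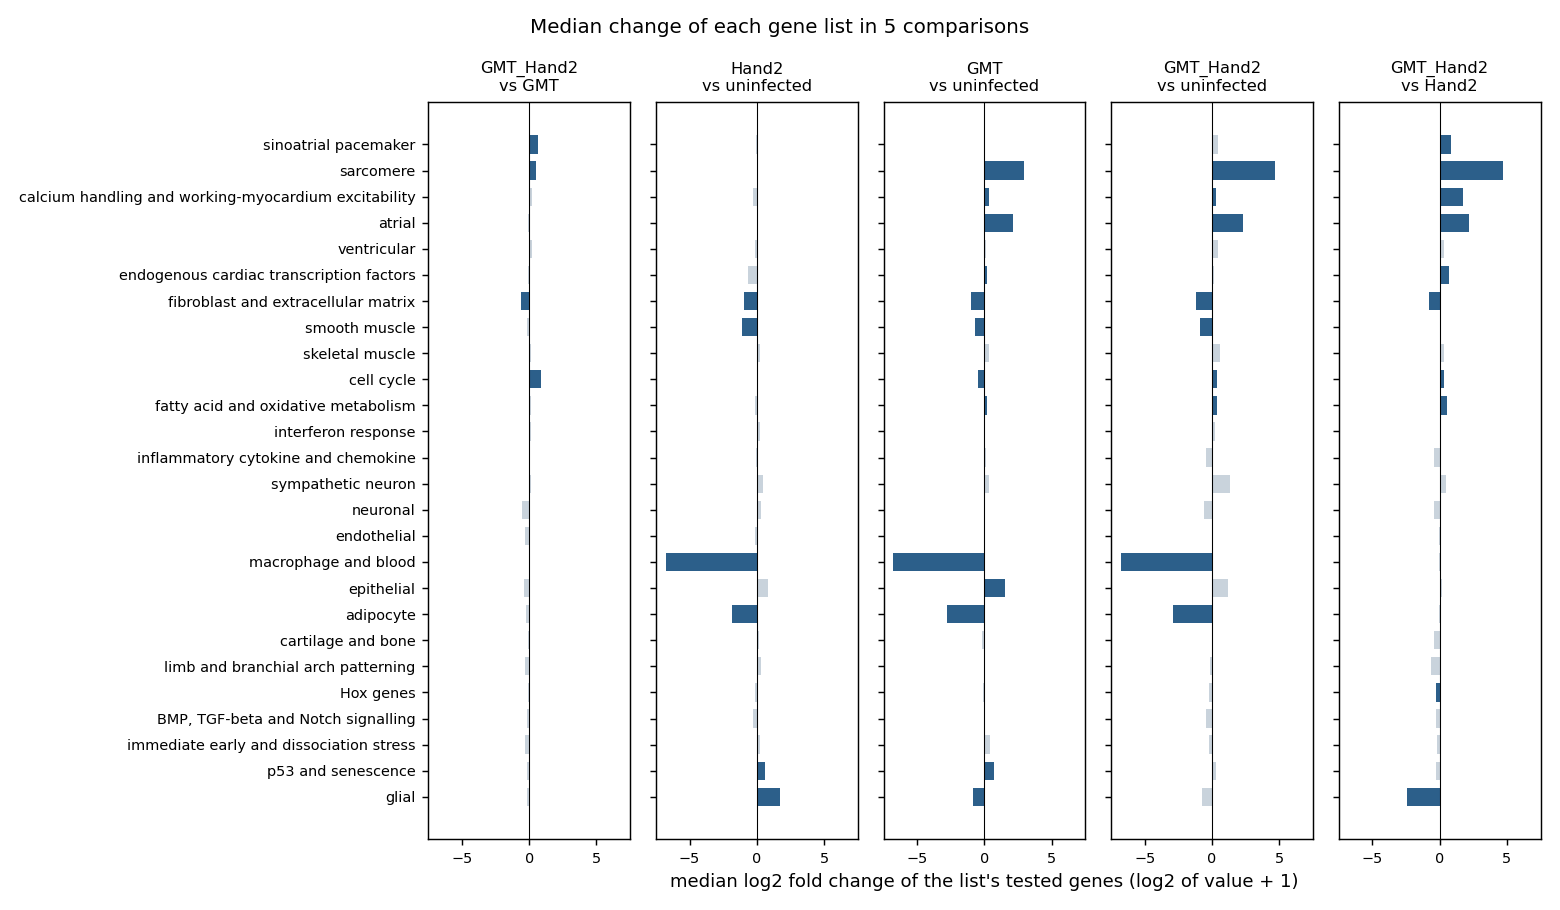
Median log2 change of the tested genes of each list (bars) in 5 comparisons, dark where the camera adjusted p with a preset correlation was below 0.05; the p of the glial list, added later, was not adjusted across lists. The sarcomere bar reaches 0.51 in GMT_Hand2 against GMT and 2.97 in GMT against uninfected cells, and the macrophage and blood bar lies between -6.74 and -6.80 in the infected groups against uninfected cells.

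Hand2 cells were compared with uninfected fibroblasts, which differ from them by infection as well as by Hand2. Changes in this comparison can therefore not be ascribed to Hand2 alone. Of 27 sarcomere genes 1 rose and 1 fell (1 higher and 1 lower adjusted over the list alone, median 0.02 and mean -0.02, of opposite sign, camera adjusted p = 0.553). Cryab, a small heat shock protein gene of muscle and other tissues, rose 2.28-fold, from 74.2 ± 4.08 to 169 ± 23.2 (log2 1.17, SE 0.20, adjusted p = 0.0232), and the M-band gene Myom1 fell 12.1-fold (adjusted p = 0.00249). Tnnt2 was at 7.97 ± 1.63 against 4.42 ± 0.959 (log2 0.73, adjusted p = 0.128) and did not pass, and Myl7, Actc1 and Nppa stayed below 1 in every Hand2 and uninfected library. Tbx3, a transcription factor of the pacemaker and conduction system, rose 4.62-fold to 30.2 ± 15.7 (log2 1.96, SE 0.42, adjusted p = 0.0479), and the T-type calcium channel gene Cacna1h, which serves pacemaking, rose 6.54-fold to 35.0 ± 20.7 (log2 2.37, SE 0.40, adjusted p = 0.0217). Hcn4 was at 0.151 and 1.66 against 0.215 and 0.403 and did not pass (adjusted p = 0.860). Of 17 pacemaker genes 2 rose and 1 fell, the protocadherin gene Pcdh17 by 12.6-fold (3 higher and 3 lower adjusted over the list alone, median -0.05, camera adjusted p = 0.911).

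The largest rises under Hand2 alone, after Hand2 itself, were those of Padi2, Igsf11, Kcnj12 and Igsf21. Padi2, a peptidylarginine deiminase gene (chromosome 4, 140906360 to 140952586), rose 67.2-fold from 1.78 ± 0.474 to 119.9 ± 10.3 (log2 5.45, SE 0.41, adjusted p = 0.000758), and the potassium channel gene Kcnj12 rose from 0.101 ± 0.0348 to 33.5 ± 26.9 (log2 4.71, adjusted p = 0.00596). The adhesion molecule genes Igsf11 and Igsf21 rose to 61.6 ± 39.1 and 24.5 ± 5.85 (log2 5.20 and 4.59, adjusted p = 0.0260 and 0.000284). The neuronal tubulin gene Tubb3 rose 7.16-fold (adjusted p = 0.0124), and Ccl7, a monocyte-attracting chemokine gene, rose 4.16-fold (adjusted p = 0.00374). Tubb3 and Ccl7 also passed as higher in GMT against uninfected cells, without delivered Hand2.

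Macrophage transcripts were almost gone from Hand2 cells. C1qa, a complement gene of tissue macrophages (chromosome 4, 136895916 to 136898844), read 337 and 680.0 in the uninfected libraries and 0 in both Hand2 libraries. Lyz2, the macrophage lysozyme gene, stood at 1207 ± 652 against 2.69 ± 2.18 (log2 -8.38, SE 0.57, adjusted p = 0.000514), and the scavenger receptor gene Stab1 at 698 ± 84.7 against 0.719 ± 0.330 (log2 -8.68, adjusted p = 7.27e-05). All 15 macrophage and blood genes tested fell (0 higher and 15 lower adjusted over the list alone), with a median of -6.77 (camera adjusted p = 1.37e-27, adjusted p = 0.223 with an estimated correlation). The median gene kept 0.0921% of its uninfected level. On the adipocyte list Cd36, a fatty acid transporter gene that macrophages also use, dropped from 122 ± 15.0 to 0.344 ± 0.456 (log2 -6.55, adjusted p = 0.000284). Of 11 adipocyte genes 6 fell (0 higher and 8 lower adjusted over the list alone, median -1.86, camera adjusted p = 4.40e-08, adjusted p = 0.223 with an estimated correlation). Infection, by the labels GFP, and possibly sorting separated these groups as well as Hand2 did, so these losses cannot be ascribed to the factor.

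In the same libraries, 3 fibroblast and matrix genes and 3 smooth muscle genes fell. Lox fell 7.13-fold, from 7434 ± 1088 to 1043 ± 189 (log2 -2.84, SE 0.40, adjusted p = 0.0109), the elastin gene Eln fell 15.6-fold and Bgn 4.11-fold (adjusted p = 0.0175 and 0.00249), while Postn and Col1a1 did not pass (adjusted p = 0.172 and 0.194). By limma 3 of 30 fibroblast genes fell (1 higher and 10 lower adjusted over the list alone), with a median of -0.92 (camera adjusted p = 0.00128, adjusted p = 0.306 with an estimated correlation). The smooth muscle genes Myh11, Lmod1 and Tpm2 fell 9.03, 3.40 and 2.89-fold, 3 of 16 on their list (0 higher and 5 lower adjusted over the list alone, median -1.09, camera adjusted p = 0.00119, adjusted p = 0.692 with an estimated correlation). Eda2r, a p53 target gene, rose 2.39-fold, 1 of 12 on the p53 list (3 higher and 0 lower adjusted over the list alone, median 0.62, camera adjusted p = 0.00230, adjusted p = 0.692 with an estimated correlation). The p53 list was lost without Hand2 replicate 1 (median 0.31, adjusted p = 0.0531). The limb gene Grem1, which encodes a BMP antagonist, fell 10.1-fold (adjusted p = 0.0118). Eln, Bgn, Lmod1 and Eda2r also passed in the same direction in GMT against uninfected cells, without delivered Hand2.

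Limma placed 823 genes apart between Hand2 and uninfected cells, 242 higher and 581 lower, of which 761 changed at least 2-fold. Of the 823, 290 did not reach a level of 1 in 2 infected libraries. The count was 51 and 29 without uninfected replicates 1 and 2, and 464 without Hand2 replicate 1. Of 45 named genes that passed, Hand2, Lyz2, Stab1, Cd36 and Igsf21 passed in all 8 fits that left out 1 library. Without uninfected replicates 1 and 2, 7 and 5 passed of the 38 still tested, without Hand2 replicates 1 and 2, 24 and 32 of 45, without either GMT library 40, and without either GMT_Hand2 library 36. The interferon list, not called over all libraries (median 0.23, camera adjusted p = 0.506), followed single Hand2 libraries, with a median of 1.57 (adjusted p = 1.75e-06) without replicate 1 and -0.93 (adjusted p = 0.0231) without replicate 2. The immediate early list was called without uninfected replicate 1 (median 0.92) and the cardiac transcription factor list without uninfected replicate 2 (-0.49).

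GMT against uninfected cells compares cells given the 3 factors with the starting cells. Infection, by the labels GFP, and possibly sorting separated these groups as well. Tnnt2 rose 92.8-fold, from 4.42 ± 0.959 to 411 ± 21.3 (log2 6.26, SE 0.22, adjusted p = 0.000111). Myl7 rose from 0.178 ± 0.0738 to 208 ± 92.5 (log2 7.40, SE 0.36, adjusted p = 0.000165), Actc1 to 42.9 ± 16.3 (log2 5.31), the M-band gene Myom2 to 70.4 ± 29.3 (log2 5.86) and Nppa to 82.8 ± 29.2 (log2 6.07). The desmosome gene Dsp, which joins heart muscle cells, rose 501-fold to 847 ± 108 (log2 8.30, SE 0.68, adjusted p = 0.000996). Of 27 sarcomere genes 16 rose and 0 fell (18 higher and 0 lower adjusted over the list alone), with a median of 2.97 (camera adjusted p = 5.91e-19, adjusted p = 0.0701 with an estimated correlation). Of 14 atrial genes 8 rose (9 higher and 1 lower adjusted over the list alone), with a median of 2.11 (camera adjusted p = 2.02e-08, adjusted p = 0.105 with an estimated correlation). The secreted chaperone gene Clu, on the atrial list, rose 59.5-fold to 1547 ± 689 (log2 5.78, adjusted p = 0.000433).

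Ryr2, the calcium release channel gene of heart muscle (chromosome 13, 11553103 to 12106945), rose 188-fold to 128 ± 97.5 (log2 6.02, SE 0.51, adjusted p = 0.00117), and the gap junction gene Gja5 rose 170.3-fold (adjusted p = 0.000434). On the calcium handling list 4 of 18 rose (6 higher and 0 lower adjusted over the list alone, median 0.35, camera adjusted p = 0.000863, adjusted p = 0.369 with an estimated correlation). The cardiac transcription factor genes Tbx20, Tbx2 and Smarcd3 rose 105, 6.39 and 2.52-fold, 3 of 16 on their list (3 higher and 0 lower adjusted over the list alone, median 0.22, camera adjusted p = 0.00730, adjusted p = 0.418 with an estimated correlation). That list was lost without GMT replicate 2 (median 0.17, adjusted p = 0.136). Among pacemaker genes, Kcnj5, a channel gene of vagal slowing, rose to 12.7 ± 8.50 from 0.0307 ± 0.0435 (log2 3.58, adjusted p = 0.00483), Popdc2 rose 6.19-fold and Tbx18 2.58-fold (adjusted p = 0.0347 and 0.0338), while Cacna1g fell 3.29-fold. The pacemaker list was not called (4 of 17 rose and 2 fell, 5 higher and 3 lower adjusted over the list alone, median 0.06, camera adjusted p = 0.475). Hcn4, at 3.69 ± 3.84, and Tbx3, at 25.2 ± 5.80, did not pass (adjusted p = 0.417 and 0.0655).

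In libraries that again lacked most macrophage transcripts, 5 fibroblast genes fell and 25 did not pass. Postn fell 8.81-fold, from 4342 ± 133 to 493 ± 241 (log2 -3.23, SE 0.38, adjusted p = 0.00485), Eln 37.9-fold and the surface marker gene Thy1 4.05-fold (adjusted p = 0.00542 and 0.0140). Of 30 fibroblast genes 5 fell (0 higher and 7 lower adjusted over the list alone, median -0.97, camera adjusted p = 7.34e-06, adjusted p = 0.105 with an estimated correlation). Lyz2 went from 1207 ± 652 to 0.163 ± 0.146 (log2 -9.91, adjusted p = 0.000246). Of 15 macrophage and blood genes 14 fell (0 higher and 14 lower adjusted over the list alone), with a median of -6.80 (camera adjusted p = 6.59e-28, adjusted p = 0.105 with an estimated correlation), or -6.71 with genes that had no reads in a group set at 3 reads per library. Adipocyte genes had a median of -2.78, with 6 of 11 falling (0 higher and 10 lower adjusted over the list alone, camera adjusted p = 4.91e-09, adjusted p = 0.105 with an estimated correlation). The cell cycle gene Pcna fell 1.64-fold (adjusted p = 0.0392, but 0.0566 with edgeR), and the cell cycle list was lower (1 of 26, 0 higher and 0 lower adjusted over the list alone, median -0.49, camera adjusted p = 8.63e-05, adjusted p = 0.454 with an estimated correlation).

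The intermediate filament gene Des rose 7.17-fold and the pericyte gene Rgs5 fell 10.8-fold on a smooth muscle list that was lower (1 rose, 2 of 16 fell, 1 higher and 4 lower adjusted over the list alone, median -0.72, camera adjusted p = 0.00777, adjusted p = 0.483 with an estimated correlation). It was lost without GMT replicate 2 (median -0.35, adjusted p = 0.213). Pdk4, a regulator of fuel use, rose 6.62-fold on the metabolism list (2 of 21, 2 higher and 0 lower adjusted over the list alone, median 0.20, camera adjusted p = 0.00740, adjusted p = 0.418 with an estimated correlation). This too was lost without GMT replicate 2 (median 0.08, adjusted p = 0.237). The keratin gene Krt18 and the mesothelial gene Msln rose 30.2 and 12.2-fold (Msln not with edgeR, adjusted p = 0.0529) on the epithelial list (2 of 9, 2 higher and 0 lower adjusted over the list alone, median 1.55, camera adjusted p = 0.00464, adjusted p = 0.288 with an estimated correlation). Eda2r rose 2.22-fold on the p53 list (1 of 12, 1 higher and 0 lower adjusted over the list alone, median 0.70, camera adjusted p = 0.00328, adjusted p = 0.483 with an estimated correlation), lost without GMT replicate 1 (median 0.23, adjusted p = 0.201). Lists gained by leaving out 1 library were the immediate early list without uninfected replicate 1 (median 1.14) or GMT replicate 1 (0.90), the ventricular list without GMT replicate 1 (0.28) and the skeletal muscle list without GMT replicate 2 (0.87).

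Limma placed 815 genes apart between GMT and uninfected cells, 308 higher and 507 lower, of which 767 changed at least 2-fold and 280 did not reach a level of 1 in 2 infected libraries. The count was 81 and 47 without uninfected replicates 1 and 2 and 450 without GMT replicate 2. Of 50 named genes that passed, 12 passed in all 8 fits that left out 1 library, among them Tnnt2, Myl7, Actc1, Tbx20 and Lyz2. Without uninfected replicates 1 and 2, 16 and 12 passed of the 43 still tested, without GMT replicates 1 and 2, 37 and 34 of 50, without either Hand2 library 46, and without either GMT_Hand2 library 44.

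GMT_Hand2 against uninfected cells compares cells given the 4 factors with the starting cells, with infection, by the labels GFP, and possibly sorting again differing between the groups. Tnnt2 rose 414-fold, from 4.42 ± 0.959 to 1831 ± 352 (log2 8.40, SE 0.22, adjusted p = 4.47e-05), Dsp rose from 1.69 ± 0.283 to 2856 ± 588 (log2 10.04), and Myh6 from 0.0707 ± 0.0783 to 287 ± 78.2 (log2 8.05). Hcn4 passed here, at 154 ± 126 against 0.309 ± 0.133 (log2 6.60, SE 0.84, adjusted p = 0.00394; 6 of the 8 fits that left out 1 library). Tbx18, the factor that marks the sinus node head, rose 4.69-fold and Tbx3 4.95-fold (adjusted p = 0.00281 and 0.0200), while Shox2 did not pass (adjusted p = 0.638). On the pacemaker list 7 of 17 rose and 3 fell (8 higher and 4 lower adjusted over the list alone, median 0.48, camera adjusted p = 0.0823). Without GMT_Hand2 replicate 1 it was called (median 0.45, adjusted p = 0.0440). The sorting proteolipid gene Mal, which myelinating and epithelial cells use, read 1044 and 239.9 in GMT_Hand2 against 0.441 ± 0.125 in uninfected cells (log2 8.45, adjusted p = 0.00321). Postn fell 47.9-fold, from 4342 ± 133 to 90.7 ± 30.6 (log2 -5.61, SE 0.38, adjusted p = 0.000331), and Col1a1 2.93-fold (adjusted p = 0.0289). The macrophage genes Mpeg1 and Mrc1 went from 318 ± 188 and 578 ± 331 to 0.108 ± 0.152 and 0.166 ± 0.0137, so the loss of macrophage transcripts held in this group as well.

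Of 27 sarcomere genes 18 rose and 0 fell (19 higher and 1 lower adjusted over the list alone), with a median of 4.68 (camera adjusted p = 3.83e-16, adjusted p = 0.0951 with an estimated correlation). Atrial genes had a median of 2.30 (9 of 14 rose and 1 fell, 10 higher and 2 lower adjusted over the list alone, camera adjusted p = 5.12e-05, adjusted p = 0.258 with an estimated correlation). Calcium handling genes had a median of 0.28 (7 of 18, 9 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0137, adjusted p = 0.491 with an estimated correlation). Metabolism genes had one of 0.39 (3 of 21, 6 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.00112, adjusted p = 0.387 with an estimated correlation). Fibroblast genes had a median of -1.20, with 13 of 30 lower (1 higher and 19 lower adjusted over the list alone, camera adjusted p = 3.47e-08, adjusted p = 0.102 with an estimated correlation). Macrophage genes had one of -6.74, with 14 of 15 lower (0 higher and 15 lower adjusted over the list alone, camera adjusted p = 2.22e-20, adjusted p = 0.182 with an estimated correlation). Adipocyte genes had one of -2.89, with 7 of 11 lower (0 higher and 11 lower adjusted over the list alone, camera adjusted p = 3.80e-08, adjusted p = 0.118 with an estimated correlation). Smooth muscle genes had a median of -0.86 (1 rose, 4 of 16 fell, 1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.0250, adjusted p = 0.537 with an estimated correlation). They were lost without GMT_Hand2 replicate 2 (median -0.58, adjusted p = 0.0974). Cell cycle genes had one of 0.35 (1 of 26, 1 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0385, adjusted p = 0.631 with an estimated correlation). They were lost without uninfected replicate 1 (median 0.13, adjusted p = 0.259) and without GMT_Hand2 replicate 2 (0.18, adjusted p = 0.343). Lists gained were the epithelial list without uninfected replicate 1 (1.26), either Hand2 library (1.18) or GMT_Hand2 replicate 2 (1.71), the immediate early list without uninfected replicate 2 (-0.84) and the p53 list without GMT_Hand2 replicate 2 (0.60). Limma placed 2037 genes apart, 934 higher and 1103 lower, 1713 of them at least 2-fold. Of these, 328 did not reach a level of 1 in 2 infected libraries. The count was 466 and 352 without uninfected replicates 1 and 2, and 1009 and 1003 without GMT_Hand2 replicates 1 and 2. Of 21 named genes that passed, 13 passed in all 8 fits that left out 1 library, among them Tnnt2, Dsp, Myh6, Tbx18 and Postn, and 13 of the 17 still tested passed without either uninfected library.

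GMT_Hand2 against Hand2 addresses what GMT adds where Hand2 is present, in groups both low in macrophage transcripts. If an Hcn4 reporter chose the GMT_Hand2 cells, the Hcn4 values here are no finding, and the other changes could come from that choice too. Tnnt2 stood at 1831 ± 352 against 7.97 ± 1.63, 229.8-fold higher (log2 7.67, SE 0.22, adjusted p = 0.000160). Hcn4 read 64.9 and 244 against 0.151 and 1.66, 171-fold higher (log2 6.18, SE 0.84, adjusted p = 0.00979), and passed in all 8 fits that left out 1 library. Myh6 rose 763-fold to 287 ± 78.2 (log2 7.72, adjusted p = 0.00208), and Myl7 to 201 ± 70.3 from 0.0837 ± 0.00402 (log2 7.49, adjusted p = 0.000456). Tbx18 rose 2.46-fold (adjusted p = 0.0319), while Tbx3 was alike, at 32.4 ± 11.5 and 30.2 ± 15.7 (adjusted p = 0.896). Postn fell 21.9-fold, from 1988 ± 211 to 90.7 ± 30.6 (log2 -4.48, SE 0.38, adjusted p = 0.00219). Gfap, an intermediate filament gene of glia (chromosome 11, 102887336 to 102897200), fell 40.1-fold, from 115 ± 14.9 to 2.88 ± 1.42 (log2 -4.95, SE 0.39, adjusted p = 0.00185), and the neurotrophin receptor gene Ngfr, the ectonucleotidase gene Entpd2 and the neural adhesion gene Chl1 fell 25.9, 39.8 and 44.6-fold (adjusted p = 0.0140, 0.00653 and 0.0458, Chl1 at 0.0648 with edgeR). Hand2 itself was 2.38-fold lower in GMT_Hand2 (adjusted p = 0.0153).

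Sarcomere genes had a median of 4.69, with 17 of 27 higher (21 higher and 0 lower adjusted over the list alone, camera adjusted p = 7.94e-20, adjusted p = 0.0625 with an estimated correlation). Calcium handling genes had one of 1.74 (7 of 18, 8 higher and 0 lower adjusted over the list alone, camera adjusted p = 8.62e-07, adjusted p = 0.249 with an estimated correlation). Atrial genes had one of 2.20 (9 of 14, 9 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.000103, adjusted p = 0.249 with an estimated correlation). Cardiac transcription factors had one of 0.69 (4 of 16, 5 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.000391, adjusted p = 0.249 with an estimated correlation). Metabolism genes had a median of 0.57 (5 of 21, 7 higher and 0 lower adjusted over the list alone, camera adjusted p = 4.67e-05, adjusted p = 0.249 with an estimated correlation). Pacemaker genes had one of 0.85 (5 of 17 rose and 1 fell, 5 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0358, adjusted p = 0.276 with an estimated correlation). The call was lost without Hand2 replicate 1 (median 0.42, adjusted p = 0.165). Fibroblast genes had one of -0.82, with 7 of 30 lower (1 higher and 9 lower adjusted over the list alone, camera adjusted p = 1.70e-05, adjusted p = 0.211 with an estimated correlation). Camera placed the cell cycle list higher, although by limma 0 of 26 passed (0 higher and 0 lower adjusted over the list alone, median 0.32, camera adjusted p = 0.0488, adjusted p = 0.778 with an estimated correlation). It was lost without Hand2 replicate 2 (adjusted p = 0.204) or GMT_Hand2 replicate 2 (0.13 and adjusted p = 0.615). The Hox list was lower with a median of -0.28 while 2 of its 33 genes passed as higher (0 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0488, adjusted p = 0.249 with an estimated correlation). The Hox call was lost without either uninfected library (adjusted p = 0.0624 and 0.0625), Hand2 replicate 1 (-0.19, adjusted p = 0.164) or GMT_Hand2 replicate 2 (-0.20, adjusted p = 0.147). Lists gained were limb patterning without GMT replicate 2 (-0.68), Hand2 replicate 1 (-0.78) or GMT_Hand2 replicate 2 (-0.75), the ventricular list without Hand2 replicate 2 (1.03), the p53 list without GMT_Hand2 replicate 1 (-0.48), and the interferon list without Hand2 replicates 1 (-1.06) and 2 (1.18). Limma placed 1094 genes apart, 690 higher and 404 lower, 976 of them at least 2-fold. The count was 419 and 395 without GMT_Hand2 replicates 1 and 2, 650 and 593 without Hand2 replicates 1 and 2, and 617 and 621 without uninfected replicates 1 and 2. Of 16 named genes that passed, 12 passed in all 8 fits that left out 1 library.

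The difference between the Hand2 effect with GMT and without it, the interaction, was tested in the same fit. It also takes in infection, which Hand2 cells underwent and uninfected cells did not, whereas GMT_Hand2 and GMT cells both did. The higher levels of Gata4, Tbx5 and Mef2c in GMT_Hand2 than in GMT cells, which did not pass, enter the interaction too. Hand2 was not separated from them. Tnnc1 had a log2 interaction of 3.46, with changes of 3.84 with GMT and 0.38 without (adjusted p = 0.0323), and Popdc2 one of 3.55 (adjusted p = 0.0181). For Hcn4 it was 4.63 (SE 1.19, adjusted p = 0.127) and for Tnnt2 1.42 (SE 0.30, adjusted p = 0.0814), and neither passed. Gfap and Igsf21 went the other way, with -3.38 and -3.48 (adjusted p = 0.0319 and 0.00750). Stab1 and Lcp1, genes of macrophages and blood cells that stood on no list, had the largest values among the named genes, 11.81 and 9.20 (limma adjusted p = 0.000260 and 0.000683). Uninfected cells alone held these transcripts at a high level. Stab1 and Lcp1 changed by log2 -8.68 and -7.62 without GMT, and by 3.14 and 1.58 with GMT. Limma called 347 interactions, 295 above and 52 below 0, of which 182 concerned genes that did not reach a level of 1 in 2 infected libraries. The count was 2 without either uninfected library, 196 without GMT replicate 1, 201 without Hand2 replicate 1, and 184 and 151 without GMT_Hand2 replicates 1 and 2. Of the 30 genes named in any comparison that passed this test, Lcp1 and Stab1 passed in all 8 such fits. Without either uninfected library they were the only ones of 22 still tested, and without another library 14 to 20 passed of 29 or 30. With edgeR 4 of the 30 passed, Bves, Lcp1, Mrc1 and Stab1, and Tnnc1 and Popdc2 did not (adjusted p = 0.104 and 0.0931).

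Across the 14038 genes, which are not independent replicates, the Hand2 effect with GMT and the one without it, which share no library, correlated at r = 0.212 (Spearman's rho 0.174). The r was 0.295 without GMT replicate 1, 0.0793 without GMT replicate 2 and 0.123 without GMT_Hand2 replicate 1. Limma called 34 genes in both, of which 12 were higher and 19 lower in both, where independent lists would share 1.10 and 1.90. Hand2 and Aldh3a1 were among the 12 and Lox among the 19. The GMT effects with and without Hand2 correlated at r = 0.441 (rho 0.364), and 293 genes were called in both, 218 of them higher and 65 lower in both against 15.1 and 14.6 for independent lists. In both pairs the comparisons use the same estimate of each gene's spread, so lists without a common effect can also share more genes. Tnnt2, Myl7 and Myh6 were among the 218 and Postn among the 65.

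**Figure D3:**
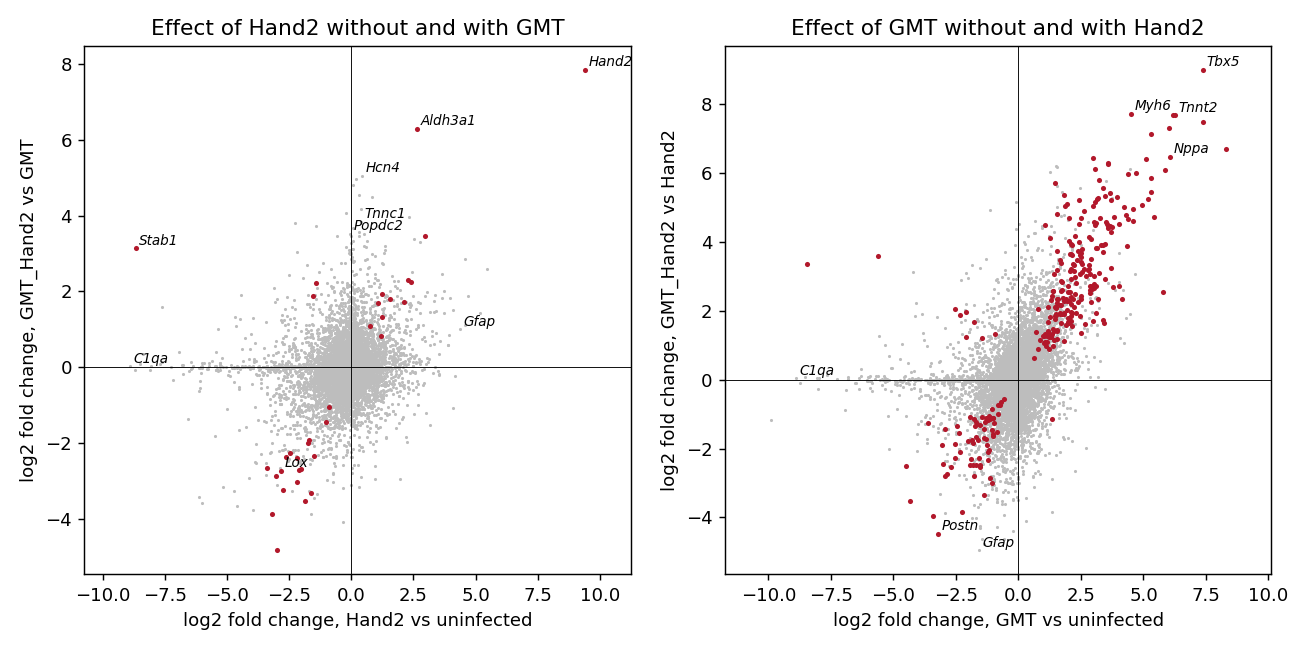
Log2 change of each of 14038 genes (points) for Hand2 without GMT (x) and with GMT (y) on the left, and for GMT without Hand2 (x) and with Hand2 (y) on the right; red points were called in both comparisons of a panel. The left panel has 34 red points and r = 0.212, and the right panel has 293 and r = 0.441, with sarcomere genes such as Tnnt2 and Myh6 at the upper right.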

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

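All tests of explanations in this part were chosen after the result was seen. The results are those where the effect of Hand2 differed with and without GMT by a test of the difference itself (limma for genes, camera for lists), which 30 named genes and 8 lists passed. Values are log2 changes with GMT minus those without. With edgeR 4 of the 30 genes passed (Bves, Lcp1, Mrc1 and Stab1), and without either uninfected library 2 of the 22 still tested (Lcp1 and Stab1). The interaction also takes in infection, which Hand2 cells underwent and uninfected cells did not, whereas GMT_Hand2 and GMT cells both did. Changes without GMT can therefore not be ascribed to Hand2. Changes with GMT were not separated from the higher levels of Gata4, Tbx5 and Mef2c in GMT_Hand2 than in GMT cells. Myh11 stood at 28.5 ± 1.57 in GMT and 90.5 ± 44.0 in uninfected cells, and Myom1 at 27.7 ± 0.797 and 51.2 ± 16.4.

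Genes with a higher value with GMT were Sfrp5 (4.77), Myh11 (4.78), Ifi27l2a (3.94), Myom1 (3.66), Aldh3a1 (3.64), Popdc2 (3.55), Tnnc1 (3.46), Mb (3.06), Bves (2.86), Tbx2 (2.21), Jph2 (1.65) and Tgfbr1 (1.47). Tnnc1, Popdc2, Mb, Bves, Sfrp5 and Aldh3a1 rose with GMT, by log2 3.84, 3.52, 2.99, 2.13, 4.96 and 6.29. Their changes without GMT were 0.38, -0.04, -0.07, -0.73, 0.19 and 2.65. Myom1, Myh11, Jph2, Tbx2, Tgfbr1 and Ifi27l2a fell without GMT, by log2 -3.34, -3.07, -1.36, -1.30, -0.77 and -2.59. With GMT they changed by 0.32, 1.71, 0.29, 0.91, 0.70 and 1.36, none of them passing there. Genes with a lower value with GMT were Igsf21 (-3.48), Inhbb (-3.46), Gfap (-3.38), Cacna1b (-3.32), Clu (-3.23) and Hand2 (-1.57), the last by its lower level in GMT_Hand2 than in Hand2 cells. Inhbb fell by 3.17 on the log2 scale with GMT, while Igsf21, Gfap and Cacna1b rose without GMT by log2 4.59, 4.38 and 3.90.

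Lists called were sarcomere (median 0.67, camera adjusted p = 0.00567, adjusted p = 0.400 with an estimated correlation), sinoatrial pacemaker (0.79, camera adjusted p = 0.0237, adjusted p = 0.400 with an estimated correlation), smooth muscle (0.87, camera adjusted p = 0.0237, adjusted p = 0.544 with an estimated correlation) and cell cycle (0.71, camera adjusted p = 5.11e-06, adjusted p = 0.400 with an estimated correlation). By limma 0 of 26 cell cycle genes passed singly (0 higher and 0 lower adjusted over the list alone). The p53 and senescence list was lower (-0.92, camera adjusted p = 0.000234, adjusted p = 0.420 with an estimated correlation), with 0 of 12 genes passing (0 higher and 0 lower adjusted over the list alone). Passing singly were 2 of 27 sarcomere genes (8 higher and 2 lower adjusted over the list alone), 2 of 17 pacemaker genes (5 higher and 0 lower adjusted over the list alone) and 1 of 16 smooth muscle genes (2 higher and 0 lower adjusted over the list alone). The pacemaker list was lost without Hand2 replicate 1 (median 0.59, adjusted p = 0.134), and the smooth muscle list without GMT replicate 2 (0.57, adjusted p = 0.287), Hand2 replicate 2 (0.68, adjusted p = 0.0508) or GMT_Hand2 replicate 1 (0.64, adjusted p = 0.104). Lists gained were immediate early without uninfected 1 (-1.38) or GMT 1 (-1.25) or Hand2 1 (-1.21) or GMT_Hand2 2 (-1.10), calcium handling without uninfected 2 (0.69) or GMT 2 (adjusted p = 0.00177) or Hand2 2 (0.67), endogenous cardiac transcription factors without uninfected 2 (0.48) or GMT 2 (0.81) or Hand2 1 (0.57), atrial without GMT 1 (-0.39) or Hand2 1 (-0.44), limb without GMT 1 (-0.79) or Hand2 1 (-0.35), fatty acid without GMT 2 (0.62), interferon response without Hand2 1 (-1.41) or Hand2 2 (0.98).

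Macrophage and blood genes (median 6.82, camera adjusted p = 1.20e-28, adjusted p = 0.318 with an estimated correlation, or 6.73 with genes without reads in a group set at 3 reads per library) and adipocyte genes (1.76, camera adjusted p = 9.86e-06, adjusted p = 0.318 with an estimated correlation) differed as well. The median macrophage gene kept 0.0401 to 0.0921% of its uninfected level in the infected groups (highest Cd14, 43.4% in GMT), and the median adipocyte gene 2.04 to 9.62% (highest Dgat2, 88.6% in Hand2). The adipocyte call was lost without uninfected replicate 1 (0.96, adjusted p = 0.0678). The named genes, some of them on neither list, were Stab1 (11.81), Lcp1 (9.20), C1qa (8.93), Lyz2 (8.73), Mrc1 (8.64), C1qc (8.58), Mpeg1 (8.01), Cd36 (5.18), Adipoq (4.05), Cidec (3.93), Plin1 (3.57) and Tnf (2.37). For 8 of them (C1qa, C1qc, Mrc1, Mpeg1, Adipoq, Cidec, Plin1 and Tnf), fewer than 2 infected libraries reached a level of 1, and fitted changes of genes with few or no reads depend on the pseudocount.

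The first pattern weighed is the loss of macrophage and blood transcripts in all 3 infected groups. In GMT and Hand2 cells the smaller fall of the list's median was -6.77, which restates the pattern and tests no explanation. Macrophages present in the uninfected libraries and nearly absent after infection and sorting remain a candidate explanation. The highest of the infected groups' medians was 0.0921% of the uninfected level, and Lyz2 went from 1207 ± 652 to 0.163 ± 0.146, 2.69 ± 2.18 and 0.548 ± 0.664. A loss caused by infection itself, or by culture conditions of infected cells, was not separated from the sort.

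Another pattern is the rise of glial genes in cells given Hand2 alone, which the glial list shows in the interaction (median -1.58, camera adjusted p = 0.000243, adjusted p = 0.221 with an estimated correlation, with no other list adjusted for). The list was written after Gfap and Ngfr had drawn attention, and it holds both, so it describes the pattern and is no independent test of it. Whether Hand2 raises these genes wherever it is delivered stays open: from GMT to GMT_Hand2 the list's median was -0.13 (SD of members 1.53), 1.89 below that of Hand2 against uninfected cells, but members went both ways. Pou3f1 and Mal had larger log2 changes with GMT than without (3.38 against 2.53, and 3.97 against 2.32), and Gfap and Sox10 smaller ones, at 2.88 ± 1.42 against 0.974 ± 0.875 and 34.3 ± 11.8 against 19.1 ± 17.5, none of them passing over all genes with GMT. A larger share of glial-lineage cells among the sorted Hand2 cells and an action of Hand2 that GMT blocks both stay open: that 90% of the 10 list genes past the threshold over the list alone were higher decides nothing, since the genes were chosen for the pattern.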

How the results depend on the processing

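The edgeR test, planned for counts, was run on the recovered reads after the data were seen. The edgeR fit with the block, the test of genes seen in infected libraries, the fits without a library of another group, the refits of all 30 interaction genes and the glial list were chosen then. For GMT_Hand2 against GMT, 110 genes by limma became 799 with DESeq2, 41 with edgeR (39 of them shared), 332 with the replicate block, 230 with edgeR and the block, and 1 in a fit of the compared groups alone, with 2 residual degrees of freedom, against 1661 at an unadjusted p under 0.05. It ran from 2 to 91 without 1 library. In Hand2 against uninfected cells, 823 became 1820 with DESeq2, 1495 with the block, 1427 with edgeR and the block and 359 among genes seen in infected libraries, with 29 to 839 without 1 library. In GMT against uninfected cells, 815 became 1792, 1358, 1375 and 353 in the same order, with 47 to 825 without 1 library. In GMT_Hand2 against uninfected cells, 2037 became 3353 with DESeq2, 3157 with the block and 3324 with edgeR and the block, with 352 to 2128 without 1 library. In GMT_Hand2 against Hand2, 1094 became 2382, 2015 and 1976 in the same order and 416 in a fit of the compared groups alone, with 395 to 1146 without 1 library. The 347 interactions became 984 with DESeq2, 671 with the block, 82 with edgeR and 54 among genes seen in infected libraries, with 2 to 269 without 1 library. In the simulation DESeq2 made 83 false calls of 231, and a fit with fewer libraries has fewer degrees of freedom; other causes were not tested. With an estimated correlation camera called 0 lists in each of the 6 comparisons, against 4, 5, 12, 9, 9 and 7 with the preset one, in the order GMT_Hand2 with GMT, Hand2, GMT and GMT_Hand2 with uninfected, GMT_Hand2 with Hand2, and the interaction. Without 1 library the lists called numbered 4 to 8, 5 to 6, 10 to 13, 9 to 10, 8 to 10 and 6 to 11. The correlation of the Hand2 effects ran from 0.0793 to 0.295 and that of the GMT effects from 0.334 to 0.522 without 1 library, and the latter was 0.526 among genes seen in infected libraries. Camera's direction for the interferon list, not called over all libraries, reversed without Hand2 replicate 2, where its medians were -0.93 in Hand2 against uninfected cells, 1.18 in GMT_Hand2 against Hand2 and 0.98 in the interaction. Over all libraries they were 0.23, 0.10 and -0.25, so the median of GMT_Hand2 against Hand2 kept its sign, and without replicate 1 they were 1.57, -1.06 and -1.41. The cause was not tested.

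The replicate numbers do not pair the samples by any label. Deviations of same-numbered libraries from their group means correlated at 0.689 between GMT and GMT_Hand2, 0.579 between GMT and Hand2, 0.507 between Hand2 and GMT_Hand2 and 0.140 to 0.250 with uninfected cells, over only 2 numbers. The block changed 1 list call, limb and branchial arch patterning in GMT_Hand2 against Hand2 (median -0.66, adjusted p = 0.0357, gained). Of 163 named calls, 162 were kept with relative log expression factors, 162 with DESeq2, 163 with the block, 161 at a log2 fold of at least 1, 154 with a pseudocount of 0.1, 132 with edgeR, 131 with no filter, 112 of 152 in fits of the compared groups alone and from 49 of 143 to 139 of 163 without 1 library, and 0 reversed in any of these settings. Of 55 named values that did not pass, 12 passed with DESeq2, 9 with the block and 10 with edgeR and the block, among them Hcn4 in GMT_Hand2 against GMT (adjusted p = 0.00480, 0.0127 and 0.0180), Postn there (6.83e-07, 0.0309 and 0.0438) and Tbx3 in GMT against uninfected cells (0.000594, 0.00609 and 0.00637). Myh6 in GMT_Hand2 against GMT passed with the block (0.0240) and with edgeR and the block (0.0362), and so did the interaction of Hcn4 (0.0168 and 0.0471). A single read was worth 0.0126 to 0.0222, so genes below the filter of 1, such as Isl1 and Nkx2-5, were read but not tested.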

Other observations

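All tests of explanations in this part were chosen after the result was seen. The glial list, added then, had a median log2 of 1.76 in Hand2 against uninfected cells (2 of 19 genes rose and 0 fell, 9 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.38e-05, adjusted p = 0.170 with an estimated correlation). Gfap stood at 4.59 ± 0.531 in uninfected, 115 ± 14.9 in Hand2, 0.974 ± 0.875 in GMT and 2.88 ± 1.42 in GMT_Hand2 cells. Sox10, the transcription factor gene of neural crest and glia, stood at 16.6 ± 8.08, 108 ± 17.6, 19.1 ± 17.5 and 34.3 ± 11.8 in the same order, and Ngfr at 87.2 ± 34.1, 544 ± 32.8, 41.1 ± 37.3 and 21.0 ± 12.6. In Hand2 against uninfected cells Gfap passed over all genes (limma adjusted p = 0.00153), while Sox10 and Ngfr did not (limma adjusted p = 0.0815 and 0.0991). The myelin gene Mbp did not pass either, at 11.8 ± 2.16 in uninfected and 4.47 ± 2.24 in Hand2 cells (limma adjusted p = 0.240). From Hand2 to GMT_Hand2 the list's median was -2.41 (1 rose and 8 fell, 1 higher and 9 lower adjusted over the list alone, camera adjusted p = 1.12e-06, adjusted p = 0.127 with an estimated correlation), from uninfected to GMT -0.82 (0 rose and 1 fell, 1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0321, adjusted p = 0.445 with an estimated correlation), and from GMT to GMT_Hand2 -0.13 (0 passed, 1 higher and 0 lower adjusted over the list alone).

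The fold changes in the authors' deposited table were compared with the library columns beside them. They give Hand2 a log2 change of 0.01 between the groups named GMT and GHMT and Gata4 one of 5.36 between those named uninfected and HAND2, whereas Hand2 read 2.71 and 3.51 in the GMT columns and 942 and 933 in the GMT_Hand2 columns, and Gata4 at most 3.92 in the uninfected and Hand2 columns. The deposited log2 changes matched groups that each average 1 GMT library and 1 Hand2 library. With GMT as GMT 2 and Hand2 2, and HAND2 as GMT 1 and Hand2 1, the log2 changes recomputed from the columns differed from the deposited ones by a median of 5.26e-05 over 10639 genes, 100% within 0.01. No other split had more than 3.67% within 0.01. With the groups as the columns are labelled the median difference was 0.191, with 2.83% within 0.01. That the columns themselves are swapped instead is excluded, since the lowest Hand2 level in a Hand2 column was 530 times the highest in a GMT column. The authors' deposited table calls 841 genes between GMT and GHMT, 1054 between HAND2 and GHMT, 541 between HAND2 and GMT, and 3464, 1695 and 2455 between uninfected and GHMT, GMT and HAND2. If its p-values used the same mixed groups, the counts that name GMT or HAND2 do not compare the groups as labelled.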
